A study of Mus musculus with 6 samples.

How the data were processed

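Total RNA of 6 cultures, 3 of mouse ES cells and 3 of epiblast stem cells, was extracted with TRIzol, labelled with Cy3 and hybridised to 1-colour Agilent arrays of 45018 spots, per the labels' protocols and the file headers. The deposited scanner files give each spot's intensity on a linear scale, and per the file headers they were made by Agilent Feature Extraction 9.1.3.1 with spatial and multiplicative detrending on and local background subtraction off. The processed signal is detrended and background-adjusted within each array and is not normalized between arrays. The series' value table, also an intensity deposited by the authors, was set against each array's processed signal and differed by at most 0.00716 on the log2 scale. It is therefore that signal rounded, on a linear scale, uncentred and with no ratio, and its column medians were 78.9, 84.9 and 68.7 for mES replicates 1 to 3 and 117, 80.25 and 82.95 for EpiSC replicates 1 to 3. The table held 0 per-sample columns that were not used. The genome build of the probes is not given in the sources used here, and no coordinates are given.

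Control spots were left out, as were spots marked as outliers by Feature Extraction (12 to 24 per array), and 0 spots were saturated. The log2 processed signal was scaled by subtracting each array's 75th percentile, and the spots of 1 probe were averaged (245 probes had 10 spots each), which left 41174 probes. Of these, 22951 (55.7%) were named through their RefSeq accession with a table of the assembly GRCm38.p6, and 18223 kept the name in the scanner file, which can be old. A probe entered if it was well above background on every array of at least 1 group and had at most 1 missing value among the 3 arrays of each group. A gene was represented by its entering probe with the highest mean over all 6 arrays. Of 6413 genes with more than 1 entering probe, 2610 had a probe past the threshold and 44 had probes past it in both directions.

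Groups were compared with limma 3.58.1 in R 4.3.3, by lmFit and eBayes with no covariate, and p-values were adjusted by the Benjamini-Hochberg method over all 20688 genes, with a threshold of 0.05. All tests were two-sided. All adjusted p-values of genes are limma's, errors of log2 fold changes are its standard errors, and a signed log2 fold change is EpiSC minus mES. The residual degrees of freedom were 4 and the prior degrees of freedom 2.47, and the median standard error was 0.241. Where a gene was not well above background on any array of 1 group by any of its probes, the fold is a bound, the mean of the bright group over the mean, per dim array, of the higher of the gene's own signal and the lowest signal well above background. Of the genes past the threshold, 263 were not above background in mES and 172 not in EpiSC.

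The arrays lay on 4 slides, which were also the 4 scans, and each slide held 1 group only. mES replicates 1 and 3 shared a slide, as did EpiSC replicates 2 and 3, and so the slide was tried as a random block. The fitted correlation of arrays on a slide was negative (-0.68). As each slide held 1 group only, a negative correlation lowers the errors of the group difference, and calls gained in that fit are not support. Replicate 3 of each group lay at position 1 of its slide and the other arrays at position 4, and the position was therefore tried as a block and within each position. No pair of arrays held identical values. The replicate numbers follow the order of deposit and pair nothing.

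There were 25 gene lists, written from general knowledge before the data were examined: core pluripotency, inner cell mass and naive ES, postimplantation epiblast, primitive streak and mesendoderm, neural ectoderm, primitive and visceral endoderm, trophectoderm, germ cell, Nodal and Activin, FGF and ERK, LIF and STAT3, BMP and Wnt signalling, DNA methylation and Polycomb, epithelial and mesenchymal, embryonic fibroblast feeder, cell cycle, imprinted, glycolysis, cytochrome c oxidase, MHC class I, stress response, housekeeping, Y-linked and Xist. Some genes stand in more than 1 list, and some members of the epithelial and mesenchymal list are expressed by fibroblasts too. The 24 lists with at least 3 measured members were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry, which asks whether a list's own genes move one way on balance. With the preset correlation 13 lists passed, by fry 10, and with an estimated correlation 0 (6 at an unadjusted p under 0.05).

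The genes named in the text follow a rule fixed before the data were examined. It takes the 10 largest changes in each direction among genes past the threshold whose groups do not overlap and which have a gene symbol, a fixed set of pluripotency and lineage genes whatever their values, up to 3 members of each list past the threshold in each direction, and the 5 largest differences in each direction between the passages. Klf2, Col1a1, Ddx3y, Eif2s3y, Kdm5d and Uty were named outside this rule, after their values were seen. The passages were compared by folds only, and a list's median was set among those of 10000 random lists matched on mean signal.

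The group tests of genes and of lists were tried on simulated data of 3 arrays against 3, drawn from the means and spreads of the 20688 genes with 200 genes changed. The passage comparison was not simulated. Of 50 genes per size, limma recovered 0% at 1.5-fold, 2% at 2-fold, 56% at 4-fold and 88% at 16-fold, and called 2 of 20471 unchanged genes. A shifted list was called, and 0 of 23 others. The genes were drawn independently, whereas the estimated correlation of members was 0.57 for the epiblast list and 0.73 for the fibroblast list. The simulation therefore does not show how often unshifted lists are called in the real data. With few changed genes the adjustment is stricter than in the real comparison. The alternatives were other background corrections, scalings, filters, probe rules and variance models, the 2 EpiSC-7 arrays averaged, the slide as a block and each array left out in turn. Chosen after the data were seen were the position as a block, the arrays at position 4 alone, the arrays low in fibroblast markers left out together, and a stricter rule on missing values. The last was the rule of a first run and was relaxed after it. Esrrb is tested under either rule, by its dimmer probe under the stricter one. Figures were drawn with matplotlib 3.10.9.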

Results

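Gene expression was measured on 6 Agilent arrays in mouse embryonic stem cells (mES) and in epiblast stem cells (EpiSC). ES cell lines come from the inner cell mass of the blastocyst, and EpiSC lines from the epiblast of the embryo after implantation. The mES group held 3 lines, replicate 1 (ESF122), replicate 2 (ESF175/1) and replicate 3, which one label names ESF58/2 and another ESF58/1. The EpiSC group held replicate 1 (line EpiSC-5), replicate 2 (line EpiSC-7 at passage 20) and replicate 3 (line EpiSC-7 at passage 25), so that its 3 samples came from 2 lines. Cells of both kinds grew on irradiated mouse embryonic fibroblast feeder cells, mES with LIF and EpiSC with FGF2. The median processed signal per array was 85.1, 92.3 and 74.6 for mES replicates 1 to 3 and 126, 87.2 and 90.9 for EpiSC replicates 1 to 3, and 66.2% to 75.4% of 41174 probes were well above background. The number of arrays, 3 per group, limits the precision. Each slide, which was also a scan, held 1 group only, and LIF or FGF2 went with the group. Effects of slide, scan or these factors cannot be told apart from those of the cell type. Separate cultures are named by the labels only through line and passage, and p-values measure the spread between these samples.

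The series compared the gene expression of the 2 cell types. Cer1, a secreted antagonist of Nodal, BMP and Wnt ligands, was at least 1214-fold higher in EpiSC than in mES cells (limma, adjusted p = 0.000303), and the endoderm and node transcription factor Foxa2 was 259-fold higher (log2 fold change 8.02 ± 0.69, SE, n = 3 per group, adjusted p = 0.001). Asb4 (281-fold), the retinoic acid-degrading enzyme Cyp26a1 (242-fold) and the growth factor Fgf5 (213-fold, well above background on 2 of the 3 mES arrays) also rose. With 1 array left out Fgf5's log2 fold change ranged from 6.58 to 8.90. In the other direction, Zfp42, the ES cell zinc finger gene also called Rex1, was 1476-fold lower in EpiSC (log2 fold change -10.53 ± 0.42, adjusted p = 8.09e-05), and Dppa5a fell by 10.21 ± 0.26 on the log2 scale (adjusted p = 1.63e-05). The spermatogenesis RNA-binding protein gene Rbmxl2 was at least 621-fold lower, and Stra8, which acts at the entry into meiosis, at least 693-fold lower. A gene not well above background on any array of a group, by any of its probes, is given as a bound. The bound is taken against the lowest signals well above background on those arrays. It covers the dim group's signal only, and neither the spread between arrays nor the processing. Some alternatives gave smaller folds than these bounds. Over all alternatives the measured log2 fold change ranged from 8.34 to 12.57 for Cer1. For Rbmxl2 it ranged from -11.34 to -6.98 and for Stra8 from -10.53 to -7.16.

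The other genes with the largest increases were Dkk1, a secreted Wnt antagonist (102-fold), the organizer gene Gsc (88.9-fold), the diacylglycerol kinase gene Dgkk (112-fold), Rflna (at least 87.0-fold) and the vitronectin gene Vtn (at least 54.6-fold). Dkk1 and Dgkk were well above background on 2 of the 3 mES arrays. The other largest decreases were Pramel13 (at least 342-fold), Ooep (at least 483-fold), Mael (at least 419.98-fold), Syce1 (at least 261-fold), Fmr1nb (at least 307-fold) and Dppa4 (694-fold, well above background on 1 of the 3 EpiSC arrays). Each of these 20 genes had its 3 EpiSC values on the same side of its 3 mES values, which the rule for choosing them required.

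Of 20688 genes tested, 5436 (26.3%) passed the threshold of adjusted p under 0.05 in limma, 2441 of them higher in EpiSC and 2995 lower. A fold change of at least 2 was met by 1829 of the higher and 1920 of the lower genes, and one of at least 4 by 736 and 765. With the EpiSC-7 arrays averaged, which counts this line once, 4369 genes passed, 4157 of the 5436 among them. The 3 values of one group did not overlap those of the other for 48.5% of the genes, against 10% by chance. The median log2 fold change of all genes was -0.11, and median scaling, which brought it to -0.01, called 2679 genes higher and 2397 lower. The count of calls was 2940 without EpiSC replicate 3, 3280 without EpiSC replicate 1, 3458 without mES replicate 2, 8712 with no filter on dim probes and 11789 with the slide as a random block. With only the arrays at position 4 of their slides it was 2693, and with the position as a block 5924. Of the named genes that kept their call without any 1 array, some lost it in fits of 4 arrays. At position 4 alone these included Otx2 (adjusted p = 0.0739), Sox17 (adjusted p = 0.0587), Otx1 (adjusted p = 0.0678), Map2 (adjusted p = 0.06) and Tagln (adjusted p = 0.0623). Without the arrays low in fibroblast markers they included Otx2 (adjusted p = 0.0806), Sox17 (adjusted p = 0.0638), Otx1 (adjusted p = 0.0884), Map2 (adjusted p = 0.0995), Tagln (adjusted p = 0.0719), Fgf5 (adjusted p = 0.0589), Klf4 (adjusted p = 0.0565), Tubb3 (adjusted p = 0.0672), Fgf15 (adjusted p = 0.0558) and Tet1, listed as Cxxc6 (adjusted p = 0.057). Others are named with their lists below.

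Arrays of one group resembled each other more than arrays of different groups. Across genes, Pearson's r of log2 signals was 0.965 to 0.977 for the 3 pairs of mES arrays, 0.978 to 0.980 for the 3 pairs of EpiSC arrays and 0.889 to 0.919 for the 9 pairs between groups. Genes are not independent replicates, and no p is given. Among genes above background on both arrays, 1450 to 2171 lay at least 2-fold apart within mES pairs, 1444 to 1981 within EpiSC pairs and 4018 to 5829 between groups.

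Genes of the naive state, which mark the inner cell mass and mES cells, fell in EpiSC. Of 20 measured members of this list 18 fell and 0 rose (also 18 adjusted over the list alone), with a median log2 fold change of -4.52. Besides Zfp42, the transcription factors Esrrb (64.5-fold lower, log2 fold change -6.01 ± 0.47, adjusted p = 0.00143) and Klf4 (10.5-fold lower, -3.40 ± 0.54, adjusted p = 0.00703) fell, as did the adhesion molecule gene Pecam1 (-5.14 ± 0.41, well above background on 1 of the 3 EpiSC arrays). Dppa3, a gene of the early embryo and germ line, was at least 158-fold lower (adjusted p = 0.00306; measured log2 fold change -9.72 to -7.84 with 1 array left out), and Tbx3 had a log2 fold change of -5.48 ± 1.13 (adjusted p = 0.0169). The members that did not pass were Klf2 by its brighter probe (-0.38, adjusted p = 0.172; its other probe fell, -4.45 ± 0.28, adjusted p = 0.000335) and Gbx2 (-1.44 ± 0.74, adjusted p = 0.188). By limma's camera test the list was lower than other genes (adjusted p = 3.63e-10; adjusted p = 0.0889 with an estimated correlation). Nr0b1 (-5.49 ± 1.31, adjusted p = 0.0266, above background on 2 of the 3 EpiSC arrays) passed in 2 of the 6 fits with 1 array left out (adjusted p = 0.0659 without mES replicate 3; log2 fold change -6.59 to -3.93). Tbx3 passed in 5 of the 6 (adjusted p = 0.0526 without EpiSC replicate 3; -6.20 to -4.37). Esrrb's fold rests on 2 mES arrays, as its value on mES replicate 3 is missing, and its other probe fell less (-1.64). That probe stands for Esrrb without mES replicate 1 (-1.88) or mES replicate 2 (-1.56), and without the arrays low in fibroblast markers it did not pass (-1.43, adjusted p = 0.0827). The same probe stands for Esrrb, and passed, under the rule that allows no missing value. The naive and epiblast lists were written from general knowledge of the field, which holds earlier comparisons of these cell types, and so their direction is not independent evidence.

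The core pluripotency factors did not pass the threshold, which does not show that they were unchanged. Pou5f1, the Oct4 gene, had a log2 fold change of -0.67 ± 0.37 (SE, n = 3 per group, limma adjusted p = 0.218), Sox2 of -0.93 ± 0.31 (adjusted p = 0.071) and Nanog of -0.10 ± 0.49 (adjusted p = 0.89). The groups did not overlap for Pou5f1 and Sox2. Nanog's sign turned with quantile normalization (0.0261). Of 15 measured members of the core list 1 rose and 5 fell (1 and 7 adjusted over the list alone). Foxd3 rose (1.51 ± 0.39, adjusted p = 0.0345), while Dppa4, Dppa2 (-3.73 ± 0.23) and the chromatin factor gene Utf1 (-1.79 ± 0.17, adjusted p = 0.00129) fell. The list as a whole did not pass (camera adjusted p = 0.0565; adjusted p = 0.529 with an estimated correlation), but it did by fry (adjusted p = 0.00433). It also passed with median scaling (adjusted p = 0.0468), every probe by itself (adjusted p = 0.0421), the EpiSC-7 arrays averaged (adjusted p = 0.0458), without the arrays low in fibroblast markers (adjusted p = 0.0287) and in 3 of the 6 fits with 1 array left out (lowest adjusted p = 0.0201, without EpiSC replicate 3). Sox2 passed with normexp (adjusted p = 0.0373), a mean-variance trend (adjusted p = 0.0484) and without mES replicate 1 (adjusted p = 0.0432). It also did with the slide as a random block (adjusted p = 0.0185), where the fitted correlation was negative. Foxd3 passed in 1 of the 6 fits with 1 array left out (adjusted p = 0.101 without EpiSC replicate 3) and not with the EpiSC-7 arrays averaged (adjusted p = 0.0729).

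**Figure D1:**
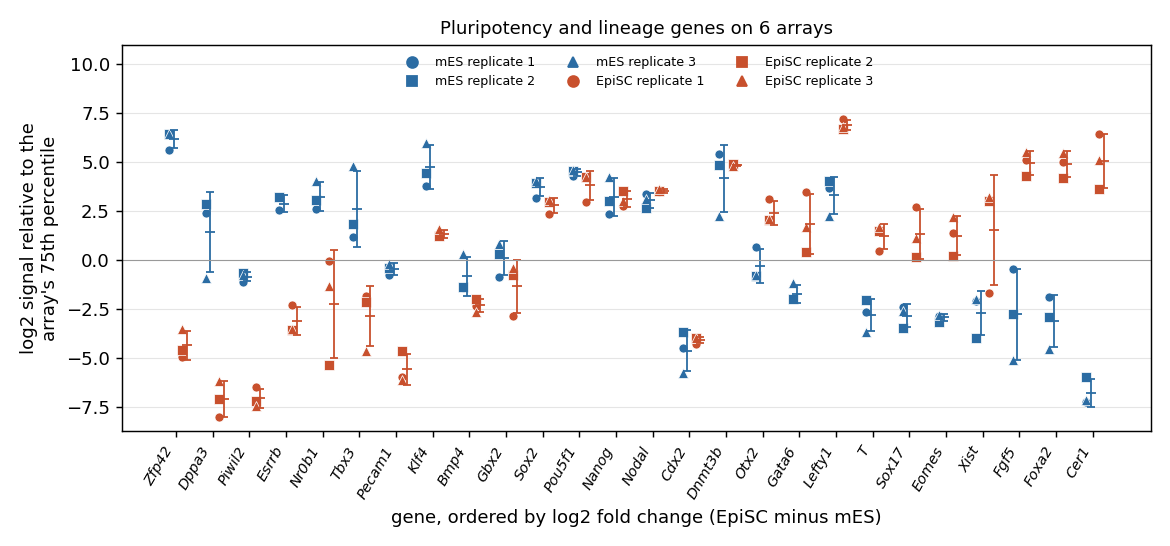
Log2 signal relative to the array's 75th percentile (vertical axis) for the pluripotency and lineage genes fixed before the data were examined, ordered by log2 fold change, with a point per array and bars for the mean ± SD of the 3 arrays of each group. Zfp42, at the left, lies near 6.16 in mES and -4.37 in EpiSC, and Cer1, at the right, near -6.80 and 5.06.

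Markers of the postimplantation epiblast were higher in part. Fgf5, Otx2, a homeobox gene of the epiblast and anterior embryo (6.5-fold, log2 fold change 2.70 ± 0.50, adjusted p = 0.0117), and the N-cadherin gene Cdh2 (27.4-fold, 4.78 ± 0.33, adjusted p = 0.000502) rose, as did the Activin antagonist gene Fst (2.71 ± 0.62, adjusted p = 0.0227). Fst passed in 2 of the 6 fits with 1 array left out (adjusted p = 0.0816 without EpiSC replicate 3) and not with the EpiSC-7 arrays averaged (adjusted p = 0.0689). The other probe of Cdh2 rose less (2.32). Of 18 measured members 5 rose and 0 fell (also 5 adjusted over the list alone), with a median log2 fold change of 0.58. The DNA methyltransferase gene Dnmt3b (0.65 ± 0.79, adjusted p = 0.558) and the ligand gene Nodal (0.50 ± 0.22, adjusted p = 0.143) did not pass, and Dnmt3b's sign turned without mES replicate 3 (-0.32). The list passed by camera (adjusted p = 0.00164; adjusted p = 0.541 with an estimated correlation), and not by fry (adjusted p = 0.146) or with only the arrays at position 4 (adjusted p = 0.124, median 0.20). At position 1, with 1 array per group, its median difference was 2.75, and mES replicate 3, the mES array at that position, held the lowest values of this list, a median of -1.87 relative to each gene's mean over the 6 arrays against 0.29 and -0.26 for mES replicates 1 and 2.

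Genes of the primitive streak and the mesendoderm it gives rise to rose in part. Brachyury (T) was 16.1-fold higher in EpiSC (log2 fold change 4.01 ± 0.49, adjusted p = 0.00324), Eomes 18.1-fold (4.18 ± 0.49, adjusted p = 0.00277), Fgf8 32.2-fold (5.01 ± 0.35, adjusted p = 0.00049) and Sox17, an endoderm factor, 17.8-fold (4.16 ± 0.65, adjusted p = 0.00682; 6.74 at its other probe). Of 21 measured members 11 rose and 1 fell (14 and 2 adjusted over the list alone), the decrease being that of Mesp2 (-1.63 ± 0.19). The median log2 fold change was 2.93, or 2.26 with the genes measured in 1 group only at their bounds (camera adjusted p = 1.25e-05; adjusted p = 0.0889 with an estimated correlation).

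Among primitive and visceral endoderm markers, Gata6, a transcription factor of the primitive endoderm, was 11.9-fold higher (3.57 ± 0.75, adjusted p = 0.0175), though 1 of its 3 probes showed no difference (0.05). The retinol-binding protein gene Rbp4 rose too (2.17 ± 0.62, adjusted p = 0.0454). It passed in 1 of the 6 fits with 1 array left out (adjusted p = 0.112 without mES replicate 2) and not with quantile normalization (adjusted p = 0.0522) or the position as a block (adjusted p = 0.064). Of 19 measured members 6 rose and 0 fell (7 and 0 adjusted over the list alone; camera adjusted p = 0.0211; adjusted p = 0.616 with an estimated correlation). The values of this list were highest on EpiSC replicate 1 (median 1.12 relative to each gene's mean, against 0.05 and 0.11 on EpiSC replicates 2 and 3). Its median difference was 1.27 at position 4 and -0.21 at position 1. The list did not pass without EpiSC replicate 1 (adjusted p = 0.115), without mES replicate 2 (adjusted p = 0.0826), by fry (adjusted p = 0.182), or without the arrays low in fibroblast markers (adjusted p = 0.0603). Gata6 passed in 3 of the 6 fits with 1 array left out (adjusted p = 0.0573 without EpiSC replicate 3).

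Neural ectoderm and trophectoderm markers moved in both directions. Sox11 (3.13 ± 0.60, adjusted p = 0.013), Otx1 (2.10 ± 0.44) and Map2 (1.01 ± 0.19) rose and the neuronal tubulin gene Tubb3 (-1.29 ± 0.18) fell, which made 3 higher and 1 lower among 17 measured neural members (the same counts, 3 and 1, adjusted over the list alone; camera adjusted p = 0.604). The median of the neural list was -0.16 and its mean 0.30, the sign of the camera test being that of the mean. Without EpiSC replicate 3 Sox11 did not pass (adjusted p = 0.0516). Its 5 other probes passed, with 3.29, 3.17, 2.93, 2.59 and 1.18. In the trophectoderm list Krt7 rose (2.74 ± 0.62, adjusted p = 0.0227), and Tfap2c (-2.48 ± 0.31), Tead4 (-1.61 ± 0.45, adjusted p = 0.043) and Esx1 (at least 17.8-fold lower) fell, 1 and 3 of 12 measured members (also 1 and 3 adjusted over the list alone; camera adjusted p = 0.948, median 0.39, mean -0.01). Cdx2, which specifies the trophectoderm, had a log2 fold change of 0.55 ± 0.50 (adjusted p = 0.444), and its sign turned with normexp (-0.0846). Krt7 (adjusted p = 0.0814 without EpiSC replicate 3) and Tead4 (adjusted p = 0.096 without EpiSC replicate 2) passed in 1 each of the 6 fits with 1 array left out. Tead4 also did not pass with quantile normalization (adjusted p = 0.0575), median scaling (adjusted p = 0.0637) or the EpiSC-7 arrays averaged (adjusted p = 0.0807).

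Germ cell genes fell the most of the lists fixed for the comparison. Of 22 measured members 19 fell and 0 rose (also 19 adjusted over the list alone). Stra8, the piRNA pathway gene Mael, the synaptonemal complex gene Sycp3 (at least 123-fold lower) and Piwil2, another piRNA pathway gene (at least 32.1-fold lower, adjusted p = 0.00012), were well above background on all 3 mES arrays and on 0 of the 3 EpiSC arrays. The median log2 fold change was -5.98, or -5.25 with the 13 members that have only a bound set at it (camera adjusted p = 8.03e-15; adjusted p = 0.0763 with an estimated correlation). With only probes above background on all 6 arrays, which removes most of these genes, the list did not pass (adjusted p = 0.0872).

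**Figure D2:**
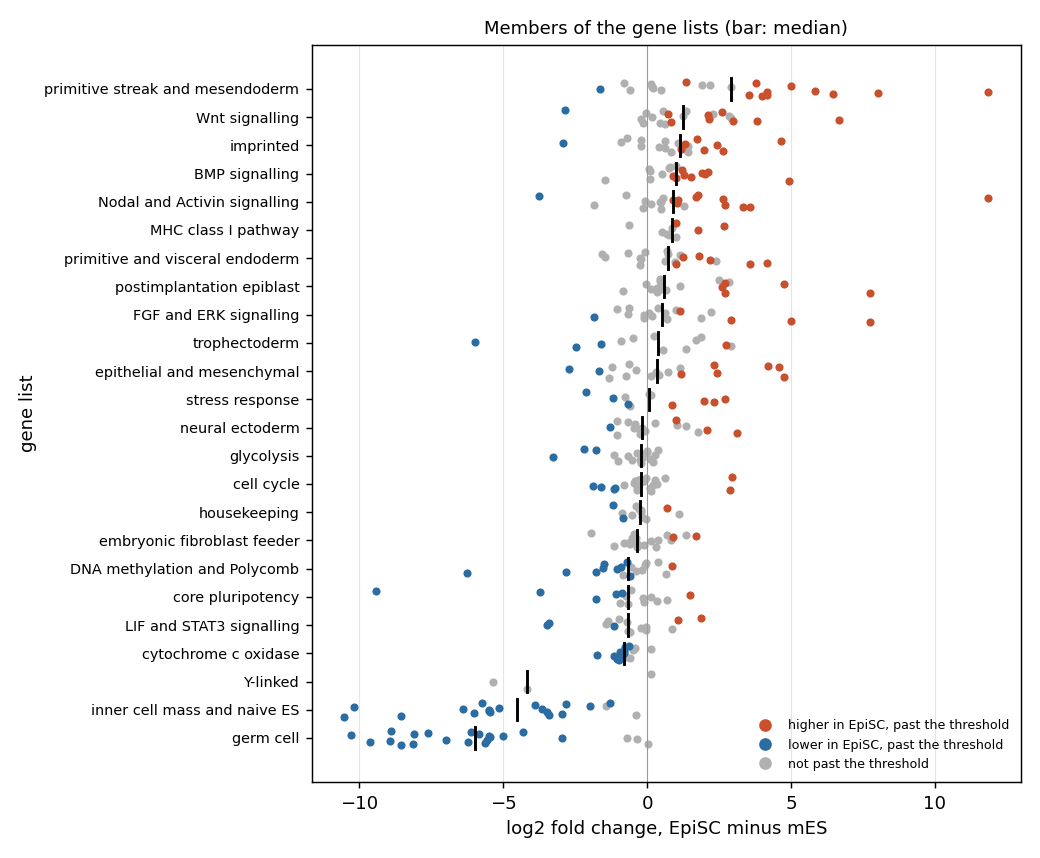
Log2 fold change, EpiSC minus mES (horizontal axis), of each measured member of the gene lists (vertical axis), coloured by direction where limma's adjusted p passed the threshold and grey elsewhere, with a black bar at each list's median. Among the 24 tested lists the germ cell and naive lists have the lowest medians, -5.98 and -4.52, and the primitive streak list the highest, 2.93.

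Among signalling genes, both Lefty genes, targets and feedback inhibitors of Nodal, rose in EpiSC, Lefty1 12.0-fold (log2 fold change 3.58 ± 0.47, adjusted p = 0.00392) and Lefty2 10.1-fold (3.33 ± 0.44, adjusted p = 0.00398). The proprotein convertase gene Pcsk6 fell (-3.76 ± 0.47). Of 21 measured Nodal and Activin members 10 rose and 1 fell (10 and 2 adjusted over the list alone; camera adjusted p = 0.000617; adjusted p = 0.0889 with an estimated correlation). In the FGF and ERK list, Fgf5, Fgf8 and Fgf15 (2.90 ± 0.39) rose and the receptor gene Fgfr4 (-1.84 ± 0.28) fell, 4 and 1 of 18 members (7 and 1 adjusted over the list alone; camera adjusted p = 0.0248; adjusted p = 0.529 with an estimated correlation). This list did not pass with quantile normalization (adjusted p = 0.0606), by fry (adjusted p = 0.051), without EpiSC replicate 3 (adjusted p = 0.128), with only the arrays at position 4 (adjusted p = 0.111) or without the arrays low in fibroblast markers (adjusted p = 0.143). Of the other probes of Fgfr4 1 passed (-1.29) and 1 did not (-0.52, adjusted p = 0.109). Fgf4 is not on this array.

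BMP pathway genes rose in part, among them the ligand gene Bmp2 (30.7-fold, log2 fold change 4.94 ± 0.77, adjusted p = 0.00686, above background on 1 of the 3 mES arrays) and the BMP target genes Id3 (2.13 ± 0.29) and Id1 (2.02 ± 0.42). Of 17 measured members 9 rose and 0 fell (9 and 1 adjusted over the list alone; camera adjusted p = 0.000106; adjusted p = 0.14 with an estimated correlation). The other 8 did not pass, among them Bmp4 with a log2 fold change of -1.48 ± 0.50 (adjusted p = 0.0715), and without mES replicate 3 one of -0.90 (adjusted p = 0.0498). With the slide as a random block, where the fitted correlation was negative, Bmp4 had an adjusted p of 0.0036. Bmp2 ranged from 4.46 to 5.85 with 1 array left out. It did not pass with the arrays at position 4 alone (adjusted p = 0.0669) or without the arrays low in fibroblast markers (adjusted p = 0.0703). Id1 passed in 4 of the 6 fits with 1 array left out (adjusted p = 0.0619 without EpiSC replicate 3). In the Wnt list Dkk1, the target gene Sp5 (3.81 ± 0.57, adjusted p = 0.00608) and the transcription factor gene Tcf7l2 (3.00 ± 0.58) rose and the Wnt antagonist gene Notum (-2.86 ± 0.36) fell. Of its 21 measured members 8 rose and 1 fell (10 and 1 adjusted over the list alone; camera adjusted p = 0.000224; adjusted p = 0.219 with an estimated correlation), with a median of 1.26, or 0.84 with bounds. Tcf7l2 did not pass without EpiSC replicate 3 (adjusted p = 0.0517). Of its 3 other probes 2 passed (2.71 and 2.68) and 1 did not (0.68, adjusted p = 0.217).

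LIF and STAT3 genes moved in both directions, and the list did not pass, with a median of -0.68. Tfcp2l1 (-3.48 ± 0.73, adjusted p = 0.0176), Klf4 and the feedback inhibitor gene Socs3 (-1.16 ± 0.24, adjusted p = 0.016) fell, while Junb (1.09 ± 0.23) and Cish (1.88 ± 0.53, adjusted p = 0.0429) rose. These were 3 and 2 of 15 measured members (6 and 2 adjusted over the list alone; camera adjusted p = 0.245). Without EpiSC replicate 3 the calls of Tfcp2l1 (adjusted p = 0.0662), Socs3 (adjusted p = 0.06), Junb (adjusted p = 0.0574) and Cish (adjusted p = 0.131) were lost. Of the 6 fits with 1 array left out, Tfcp2l1 and Junb passed in 4, Socs3 in 3 and Cish in 1. Cish did not pass with the position as a block (adjusted p = 0.0573).

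Genes of DNA methylation and of Polycomb complexes fell in part. Dnmt3l, a cofactor of the de novo DNA methyltransferases, was 76.7-fold lower in EpiSC (log2 fold change -6.26 ± 0.64, adjusted p = 0.0018), and the methylcytosine dioxygenase genes Tet2 (-2.80 ± 0.29) and Tet1, listed as Cxxc6 on the array (-1.79 ± 0.25), fell. Cbx2 rose (0.88 ± 0.20, adjusted p = 0.0226). It passed in 3 of the 6 fits with 1 array left out (adjusted p = 0.0771 without EpiSC replicate 1), not with the mean of its probes (0.57, adjusted p = 0.08) and not by its other probe (0.26). Of 18 measured members 9 fell and 1 rose (also 9 and 1 adjusted over the list alone; camera adjusted p = 0.00795; adjusted p = 0.14 with an estimated correlation).

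Among epithelial and mesenchymal genes, the simple epithelial keratin genes Krt8 (24.1-fold, log2 fold change 4.59 ± 0.75, adjusted p = 0.00774) and Krt18 (18.5-fold, 4.21 ± 0.72, adjusted p = 0.00913) rose alongside Cdh2, and the fibronectin gene Fn1 (-1.66 ± 0.33) and the claudin gene Cldn4 (-2.72 ± 0.71, adjusted p = 0.0351) fell. Of 18 measured members 6 rose and 2 fell (also 6 and 2 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.11) except with no filter on dim probes (adjusted p = 0.0196) or without EpiSC replicate 2 (adjusted p = 0.024). Cldn4 passed in 1 of the 6 fits with 1 array left out (adjusted p = 0.103 without EpiSC replicate 1) and Fn1 in 5 (adjusted p = 0.0556 without EpiSC replicate 3). With 1 array left out the fold moved by up to 1.85 times for Krt8 and 1.81 times for Krt18. Neither Krt8 nor Krt18 passed with the arrays at position 4 alone (adjusted p = 0.0701 and 0.0829) or without the arrays low in fibroblast markers (adjusted p = 0.0799 and 0.0848).

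Fibroblast markers, which feeder cells would bring, differed more between arrays of a group than between the groups. Relative to each gene's mean over the 6 arrays, the median of 21 measured fibroblast members was 0.38, -1.58 and 1.37 on mES replicates 1 to 3 and 1.13, 0.36 and -1.98 on EpiSC replicates 1 to 3. The smooth muscle genes Tagln (1.70 ± 0.33, adjusted p = 0.0134) and Acta2 (0.90 ± 0.21, adjusted p = 0.0248) rose, 2 of 21 with 0 lower (also 2 and 0 adjusted over the list alone), and the collagen gene Col1a1 had a log2 fold change of -0.35 (adjusted p = 0.859). Acta2 passed in 2 of the 6 fits with 1 array left out (adjusted p = 0.0792 without EpiSC replicate 1). Its other probes gave -0.18, 2.73 and 3.14, while that of Tagln gave 3.74. The list did not pass (camera adjusted p = 0.491, in the upward direction, with a median of -0.35 and a mean of -0.08). Its median difference was 1.36 with the arrays at position 4 (adjusted p = 0.000458), where the list passed as it did without mES replicate 3 (adjusted p = 0.0492) or EpiSC replicate 3 (adjusted p = 0.0461), and -3.44 between the arrays at position 1. Without mES replicate 2 and EpiSC replicate 3, the arrays lowest in these markers, 1546 genes passed, 829 higher and 717 lower, and 1357 of the 5436 calls remained.

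Sex-linked genes parted the EpiSC lines. Xist, the noncoding RNA of the inactive X chromosome, had a log2 signal of 3.03 and 3.24 on the EpiSC-7 arrays and of -1.69 on the EpiSC-5 array, against -2.10, -4.00 and -1.99 on mES replicates 1 to 3. The Y-linked gene Ddx3y lay at -5.12 and -8.05 on the EpiSC-7 arrays and at 0.93 on the EpiSC-5 array. Eif2s3y lay at -4.57 and -6.95 against 2.00. Kdm5d lay at -5.13 and -5.60 against -1.63, but at -6.23 on mES replicate 3, below both EpiSC-7 arrays. Between the groups Xist had a log2 fold change of 4.22 ± 1.37 (adjusted p = 0.0651), and 0 of 3 Y-linked genes passed (0 adjusted over the list alone; camera adjusted p = 0.515). Without EpiSC replicate 1 Xist passed (5.83, adjusted p = 0.00756), as did the Y-linked list (adjusted p = 0.0288). Xist also passed with a mean-variance trend (adjusted p = 0.0497). It did so too with the slide as a random block (adjusted p = 0.00807), where the fitted correlation was negative.

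**Figure D3:**
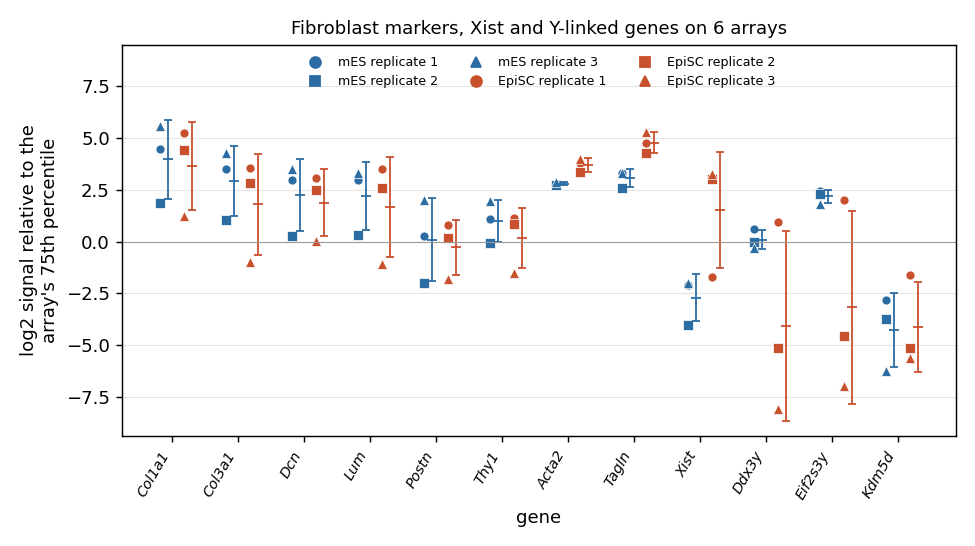
Log2 signal relative to the array's 75th percentile (vertical axis) of fibroblast markers, Xist and Y-linked genes, with a point per array and bars for the mean ± SD of the 3 arrays of each group. The fibroblast genes other than Acta2 and Tagln are lowest on mES replicate 2 and EpiSC replicate 3 within their groups, and Xist is at 3.03 and 3.24 on the EpiSC-7 arrays.

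The 2 passages of EpiSC-7 were compared without a test, since each was measured on 1 array. From passage 20 to passage 25, Pmaip1, the gene of the apoptosis protein Noxa, was 56.7-fold higher, Trim25 33.5-fold, Prnd 16.4-fold, the Wnt target and stem cell gene Lgr5 15.2-fold and Nab2 14.7-fold. Ppp1r3g was 37.3-fold lower, the angiotensin receptor gene Agtr2 28.7-fold, the haematopoietic and endothelial surface gene Cd34 17.0-fold, the endothelial claudin gene Cldn5 15.2-fold and Catsperz 14.6-fold. With normexp the log2 differences were smaller for Ppp1r3g (-3.65 against -5.22), Agtr2 (-2.79 against -4.85), Cldn5 (-2.56 against -3.92) and Prnd (2.96 against 4.04). Of 20157 genes above background on both arrays, 756 lay at least 2-fold higher at passage 25 and 1225 at least 2-fold lower, 1981 in all, against 1444 between EpiSC-5 and EpiSC-7 at passage 20 and 1688 between EpiSC-5 and EpiSC-7 at passage 25. The median difference was -0.14, and with median scaling (median 0.05) more genes lay higher (1138) than lower (764).

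Fibroblast markers were the list that differed most between the passages. Their median log2 difference, passage 25 minus passage 20, was -2.38 over 20 members, 15 of them at least 2-fold lower, at percentile 0 of 10000 random lists matched on mean signal. Glycolysis genes had a median of -0.60 (percentile 0) and cytochrome c oxidase genes of -0.38 (percentile 0.39), and 5 measured germ cell genes of -0.81 (percentile 0.88). FGF and ERK genes had a median of 0.49 (percentile 100), epithelial and mesenchymal genes of 0.39 (percentile 99.98, 7 of 18 at least 2-fold higher), primitive streak genes of 0.27 (percentile 99.9), primitive and visceral endoderm genes of 0.23 (percentile 99.49) and stress genes of 0.29 (percentile 98.37). The median of the epithelial and mesenchymal list thus had the opposite sign to that of the fibroblast list. This list mixes epithelial genes such as Krt8 with genes that fibroblasts also express, and the latter were not looked at apart. These percentiles describe the 2 arrays, which also lay at different positions of their slide.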

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

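The position on the slide (as a block and as the arrays at position 4 alone), the arrays low in fibroblast markers left out together, and the rule that allows no missing value were tests chosen after the results were seen; the others were chosen before the data were examined. The 20 genes with the largest changes stayed past the threshold in the same direction in each alternative that tested them, except 1 of the 20 with both arrays low in fibroblast markers left out. Of 101 named genes past the threshold, 74 to 92 stayed past it with 1 array left out, 65 with the arrays at position 4 alone and 51 with both arrays low in fibroblast markers left out. Over all named genes and alternatives, 2062 values kept direction and side of the threshold, 206 lost the call, 9 gained one and 9 turned sign, and for the gene lists these numbers were 491, 27, 16 and 17. The fold of 32 of 110 named genes moved by more than 1.5 times with 1 array left out, among called genes most for Esrrb (21.9 times), Nr0b1 (2.95), Dppa3 (2.25), Fgf5 (2.24), Tbx3 (2.15), Bmp2 (1.87) and Krt8 (1.85). Signal over background limits the dim genes: 263 and 172 of the genes past the threshold have only a bound.

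With no filter on dim probes 28779 genes were tested, with a median log2 fold change of -0.28, and 2594 passed as higher and 6118 as lower. The gain was thus nearly all among lower genes, and its cause was not tested. The count of genes past the threshold (5436, with 2441 higher and 2995 lower) was then 8712. It was 11789 (4987 higher, 6802 lower) with the slide as a random block, where the fitted correlation of arrays on a slide was -0.68. It was 2693 (1213 higher, 1480 lower) at position 4 alone and 1546 (829 higher, 717 lower) without the arrays low in fibroblast markers, with 4 arrays each. With 1 array left out it ranged from 2940 to 4958, the higher genes from 1378 to 2171 and the lower from 1562 to 2787. With normexp 3990 of 6423 calls were lower, and with quantile normalization 2774 of 5637. With the EpiSC-7 arrays averaged it was 4369, 4157 of them shared, and of 100 named genes tested 93 stayed past the threshold. The position as a block left 5180 of the 5436 calls past the threshold. The rule that allows no missing value gave 5436 calls, 5433 of them shared. Lists past the threshold numbered 13, and 0 with an estimated correlation.

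The core pluripotency list passed with median scaling (adjusted p = 0.0468), every probe by itself (0.0421), the EpiSC-7 arrays averaged (0.0458), fry (0.00433) and without the arrays low in fibroblast markers (0.0287), and with 1 array left out ranged from 0.0201 to 0.136. With an estimated correlation the adjusted p was 0.0889 for the naive list, 0.541 for the epiblast list and 0.0889 for the primitive streak list. The epiblast list had 0.146 by fry and 0.124 at position 4 alone. The fibroblast list passed at position 4 alone (0.000458), turned direction without the arrays low in its markers (0.768), and ranged from 0.0461 to 0.883 with 1 array left out, where it passed without mES replicate 3 or EpiSC replicate 3 and turned direction without mES replicate 2 or EpiSC replicate 1. The trophectoderm list, near 0, turned direction with normexp (0.751), quantile normalization (0.907), median scaling (0.886), probes above background on all 6 arrays (0.604), every probe by itself (0.982), position 4 alone (0.914) and fry (0.057), and ranged from 0.561 to 0.995 with 1 array left out. The cell cycle list turned with quantile normalization (0.907) and no filter (0.909), and the stress list at position 4 alone (0.994). No list passed the threshold in the turned direction; the cause was not tested.

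Nanog's log2 fold change was 0.0261 with quantile normalization and 0.46 at position 4 alone, and ranged from -0.54 to 0.41 with 1 array left out. That of Dnmt3b was -0.30 at position 4 alone and ranged from -0.32 to 1.28, and that of Cdx2 was -0.0846 with normexp, -0.0535 at position 4 alone and ranged from -0.0136 to 1.03. The gap between the lowest correlation within groups and the highest between them was 0.0467 and 0.0337 with normexp. Of the passage counts, 1981 genes at least 2-fold apart became 993 with normexp, 3694 with no filter and 250 at a fold of 4 or more; the cause was not tested. The cell line as a random block could not be fitted, since 1 line alone has 2 arrays. No paired analysis was possible because the labels give the groups no shared replicate numbers.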

Other observations

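The tests of the slide position for the fibroblast markers, of a swapped label and of a lost Y chromosome for Xist, and all tests of mES replicate 3 were chosen after the result was seen, and so was the share of low genes set beside the median below. Imprinted genes, which are expressed from 1 parental copy, rose in part. Nnat was 25.3-fold higher in EpiSC (log2 fold change 4.66 ± 0.43, SE, n = 3 per group, limma adjusted p = 0.00127) and Grb10, an inhibitor of growth factor receptors, 5.38-fold (2.43 ± 0.26, adjusted p = 0.00225), while Phlda2 was 7.66-fold lower (-2.94 ± 0.56, adjusted p = 0.0127). Peg3 rose as well (2.63 ± 0.49, adjusted p = 0.0126; 0.0512 without EpiSC replicate 3). Of 20 measured members 7 rose and 1 fell (also 7 and 1 adjusted over the list alone; camera adjusted p = 0.00419; adjusted p = 0.219 with an estimated correlation). The MHC class I list had 3 of 9 members higher and 0 lower (also 3 and 0 adjusted over the list alone), the immunoproteasome subunit gene Psmb8 (2.69 ± 0.31, adjusted p = 0.00256) and the peptide transporter gene Tap2 (1.78 ± 0.31) among them, with Psmb10 (1.02 ± 0.27, adjusted p = 0.0381) (camera adjusted p = 0.00795; adjusted p = 0.529 with an estimated correlation). Its members were lowest on mES replicate 2 (median -1.31 relative to each gene's mean), 1 of the arrays low in fibroblast markers, and without both of those arrays the list did not pass (adjusted p = 0.0676), nor did it by fry (adjusted p = 0.051). Psmb10 passed in 1 of the 6 fits with 1 array left out (adjusted p = 0.0955 without EpiSC replicate 3) and not with the EpiSC-7 arrays averaged (adjusted p = 0.0818).

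Genes of cytochrome c oxidase, the last enzyme of the respiratory chain, fell for the most part. Of 16 measured members 11 fell and 0 rose (12 and 0 adjusted over the list alone), among them Cox7a1 (-1.75 ± 0.33, SE, n = 3 per group, limma adjusted p = 0.0124), Cox6c (-1.16 ± 0.20, adjusted p = 0.00997) and Cox5a (-1.06 ± 0.17, adjusted p = 0.00692), with a median log2 fold change of -0.80 (camera adjusted p = 0.0002; adjusted p = 0.355 with an estimated correlation). In the glycolysis list 3 of 18 members fell and 0 rose (also 3 and 0 adjusted over the list alone; camera adjusted p = 0.243), the phosphofructokinase gene Pfkp by the most (-3.25 ± 0.55, adjusted p = 0.00879), with Pdk1 (-2.18 ± 0.55) and Ldhb (-1.78 ± 0.44). Pdk1 (adjusted p = 0.0959 without EpiSC replicate 1) and Ldhb (adjusted p = 0.0919 without it) passed in 2 each of the 6 fits with 1 array left out. Ldhb did not pass with the EpiSC-7 arrays averaged (adjusted p = 0.0694). Of the other probes of Pfkp 1 passed (-2.81) and 1 did not (-0.77, adjusted p = 0.0674). The glycolysis list passed without mES replicate 3 (adjusted p = 0.0492) or EpiSC replicate 2 (adjusted p = 0.0484).

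In the cell cycle list Mycl (2.94 ± 0.26, adjusted p = 0.00104) and the cyclin gene Ccnd2 (2.89 ± 0.53) rose. Cdkn1a, a cyclin-dependent kinase inhibitor gene (-1.59 ± 0.31), Cdkn2a (-1.87 ± 0.35; adjusted p = 0.0502 without EpiSC replicate 3) and the cyclin gene Ccne1 (-1.16 ± 0.17) fell, 2 and 4 of 23 members (also 2 and 4 adjusted over the list alone; camera adjusted p = 0.604). In the stress list the immediate early genes Jun (2.70 ± 0.36, adjusted p = 0.00399) and Fos (2.00 ± 0.32), with the transcription factor gene Atf3 (2.31 ± 0.48; adjusted p = 0.0625 without EpiSC replicate 3) rose. The stress kinase regulator gene Trib3 (-2.12 ± 0.25), Gadd45a (-1.20 ± 0.35, adjusted p = 0.0481) and Ddit3 (-0.66 ± 0.20, adjusted p = 0.0499) fell, 4 and 3 of 11 members (also 4 and 3 adjusted over the list alone; camera adjusted p = 0.604). Atf3 passed in 4, Gadd45a in 1 (adjusted p = 0.126 without EpiSC replicate 1) and Ddit3 in 0 of the 6 fits with 1 array left out (adjusted p = 0.13 without EpiSC replicate 3). With median scaling Gadd45a (adjusted p = 0.0923) and Ddit3 (adjusted p = 0.0572) did not pass. Gadd45a did not with quantile normalization either (adjusted p = 0.0555), nor Ddit3 with a mean-variance trend (adjusted p = 0.06), the mean of its probes (adjusted p = 0.0502), every probe by itself (adjusted p = 0.0506) or the EpiSC-7 arrays averaged (adjusted p = 0.0923). In the housekeeping list 1 rose and 2 fell of 12 members (2 and 3 adjusted over the list alone; camera adjusted p = 0.275), the transferrin receptor gene Tfrc (-1.20 ± 0.20) by the most. Hprt, used as a reference gene, fell (-0.85 ± 0.21, adjusted p = 0.0274), and Gusb rose (0.69 ± 0.20, adjusted p = 0.046). Both passed in only 1 of the 6 fits with 1 array left out (Hprt adjusted p = 0.0793 without mES replicate 2, Gusb 0.115 without EpiSC replicate 1). Hprt did not pass with median scaling (adjusted p = 0.0557), and Gusb did not with the mean of its probes (0.35, adjusted p = 0.264) or the EpiSC-7 arrays averaged (adjusted p = 0.0913).

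Some of these genes kept their call whichever array was left out but lost it in fits of 4 arrays. At position 4 alone these were Phlda2 (adjusted p = 0.0757), Cox7a1 (adjusted p = 0.0682), Cox6c (adjusted p = 0.0639), Cox5a (adjusted p = 0.0566), Cdkn1a (adjusted p = 0.0595) and Tap2 (adjusted p = 0.0564). Without the arrays low in fibroblast markers they were Phlda2 (adjusted p = 0.0822), Cox7a1 (adjusted p = 0.0848), Cox6c (adjusted p = 0.0942), Cox5a (adjusted p = 0.0762), Tap2 (adjusted p = 0.0597), Ccnd2 (adjusted p = 0.0824), Ccne1 (adjusted p = 0.0633), Pfkp (adjusted p = 0.0528) and Tfrc (adjusted p = 0.0633).

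Fibroblast markers were low on mES replicate 2 and EpiSC replicate 3: 17 of 20 measured members lay at least 2-fold lower on mES replicate 2 than on both other mES arrays, and 13 of these also at least 2-fold lower at passage 25 than at passage 20 of EpiSC-7. A position effect shared by both groups was not seen. On mES replicate 3, at the position of EpiSC replicate 3, the markers lay 0.78 above mES replicate 1, at position 4 (median, n = 20). The SD of this median over 1000 resamples of the genes, drawn as if independent, was 0.14. The other low array, mES replicate 2, lay at position 4. Position 1 held 1 array per group, each of its own line or passage, so that position was not excluded for EpiSC replicate 3. Less RNA from feeder cells on the low arrays may be the cause, but the test set for it beforehand went against it. The 534 other genes low on mES replicate 2 had a median difference between the passages of -0.34. This value lay above the bound of -0.5 that was to exclude feeder RNA. Its SD over 1000 resamples of the genes, drawn as if independent, was 0.04. After the value was seen that bound was judged badly placed, because the 534 genes may also hold genes that differ between lines for other reasons. Of them 24.0% (128) lay at least 2-fold lower at passage 25, against 6.08% of 20157 genes and 32.5 genes if the lists were independent. The 534 genes were picked for differing between arrays, so that a share above that of all genes does not by itself speak for feeder RNA. A set of 514 genes high on mES replicate 2 had a median of -0.27, so that the median hardly tells the sets apart. The share of low genes in that set was not computed. The explanation stays open, as does a difference between the lines or passages, which was not tested.

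High Xist and low Y-linked signals on both EpiSC-7 arrays were not the signal of a single probe, since 4 of 4 Xist probes lay at least 2-fold higher there than on every other array. The probes of these genes, which also show the pattern, argued against a label swapped between EpiSC-5 and 1 of the EpiSC-7 arrays. On 10 of 11 Xist and Y-linked probes both arrays labelled EpiSC-7 lay further from EpiSC-5 than from each other, and after a swap 1 line would hold an array with Y-linked signal and low Xist beside an array with the reverse. The count over all genes did not decide on a swap. At least 2-fold apart lay 1981 genes between the EpiSC-7 arrays, and 1444 and 1688 between EpiSC-5 and each of them. Loss of the Y chromosome alone would leave Xist low, and it lay 4.83 above EpiSC-5. Xist was also high on EpiSC replicate 3, where fibroblast markers were lowest. As a hypothesis, EpiSC-7 may carry an inactive X chromosome and no Y chromosome, unlike the other lines. The Y-linked gene Kdm5d did not part the EpiSC-7 arrays (-5.13 and -5.60) from mES replicate 3 (-6.23). The labels give no sex, and the difference between lines was not tested.

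On mES replicate 3, 11 of 18 epiblast members lay at least 2-fold below the other mES arrays and 8 of 19 naive members at least 2-fold above, with medians of -1.39 and 0.63. The epiblast median lay at percentile 0 of 10000 random lists matched on mean signal over the 6 arrays. A dimmer array was not excluded, as the lists were not matched on signal in mES, where members such as Fgf5 lay lower. Of the 6 arrays, mES replicate 3 had the lowest share of probes well above background (66.2%). Over the 37 genes of both lists, EpiSC replicate 3 deviated with a slope of -0.12 (SE 0.07) on the deviation of mES replicate 3. A shared effect of the position on the slide would give a slope near 1, and so the slope argues against one. With 1 array per group at position 1, an effect on mES replicate 3 alone was not excluded. Dppa3, a naive member, went the other way (-3.52). A difference of this line or culture, which has 1 array, may be the cause and was not tested.

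The 6 arrays can be split 3 against 3 in 10 ways, too few for a share under 0.05. By limma the real split gave 5436 genes past the threshold (2441 higher, 2995 lower) and each of the others 0. At an unadjusted p under 0.05 the others had 167 to 1292 genes, against 8570. For each of these counts 1 split, the real one, gave a result as large. Every other split puts both cell types on both sides, so that the difference between the cell types widens its errors. The counts of 0 thus do not show what chance alone would give. For gene lists the real split gave 13 and the highest other also 13, that of mES replicate 1 and EpiSC replicates 1 and 3 against the rest, so that 2 splits gave as many.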
